A study of Mus musculus with 4 samples.

How the data were processed

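RNA from cultures of splenic CD4+ T cells collected after 3 days was sequenced as 4 libraries, and the groups were taken from the genotype in the labels. Per the labels' protocols, total RNA was extracted with TRIzol and libraries were made and sequenced on an Illumina HiSeq instrument. Per the submitters' processing notes, Bowtie2 and RSEM were used with the GRCm38.p6 (mm10) mouse genome. Tool versions, counting options, the annotation release, and whether strand was used are not given in the sources used here, so reads of a gene and an overlapping antisense gene cannot be told apart. The deposited table held whole-number counts for 34745 genes and, beside them, FPKM values, with gene symbols, identifiers, positions and pathway annotation. The authors' deposited FPKM were scaled to column totals and to 1 fixed length per gene: for 8179 genes checked, the length implied by count and FPKM differed by more than 0.01% between libraries in 0 genes. Names were paired with identifiers by the table, in which 27 gene symbols had been turned into dates. Of 751 list members, 741 matched a symbol of the table, 9 an identifier or older symbol in reference name tables, and 1 none. Biotype and GC content came from a GENCODE annotation and its transcripts, which held 98.846% of the identifiers, all on the same chromosome.

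Counts as deposited were analysed with edgeR 4.0.16 in R 4.3.3. Low genes were removed with filterByExpr (minimum count 10, minimum total 15), libraries were scaled by trimmed mean of M values (factors 1.02, 1.02, 0.959 and 1.00 for wild type 13 and 15 and knockout-labelled 22 and 24), and the 2 groups were compared with glmQLFit and glmQLFTest, two-sided, with no covariate. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. Adjusted p-values given for single genes are from this test. The standard error of a log2 fold change was taken as its size over the square root of the F statistic and is approximate. CPM used the scaled library sizes, except for summed receptor segments, and the biological coefficient of variation was 0.157. An exact test of a single gene in 2 against 2 libraries cannot give a p below 0.333, so inference rests on the spread shared across genes. Replicates differed by more than counting noise, with a chi-square per degree of freedom of 9.94 in wild type and 30.9 in the knockout-labelled pair, and each library was counted as 1 replicate. Pearson correlations of log2 CPM across genes were 0.989 and 0.979 for these pairs, where genes are not independent replicates. Floors of 3 counts cover counting error only.

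Before the data were examined, 35 gene lists were written from general knowledge of T cell differentiation, lipid metabolism, the cell cycle, stress and the other cell types of spleen, together with the rule for named genes. The rule takes 14 genes whatever their values, the 8 largest rises and 8 largest falls past the threshold with a mean of 5 or more CPM, non-overlapping groups and a symbol that is not a predicted name, and up to 3 members of each list by adjusted p. A few genes that the rule takes are not reported here. Other members named beside a count were chosen after their values were seen. The 32 lists with 3 or more genes past the filter were tested by limma 3.58.1 camera on log2 CPM (prior count 2) with a preset correlation of 0.01, and again with an estimated correlation and with fry. The test with an estimated correlation has 2 residual degrees of freedom. It gave an adjusted p of 0.664 for each of the 9 lists called with the preset correlation. A call lost with it therefore does not tell whether correlated genes made that call. The correlation it estimated was 0.858 for E2F targets and DNA replication, 0.639 for amino acid and nutrient transport and 0.268 for p53 targets. For B cell, natural killer, follicular helper, and inhibitory and cytotoxic genes it was 0.178, 0.156, 0.0905 and 0.0358. It was -0.0265 for T helper 17 and -0.115 for gamma-delta genes. Where the estimate lies above the preset, the preset p may be too small. KEGG pathways in the table with 10 to 300 tested genes were tested in the same way.

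The tests were tried on simulated counts with known answers, drawn from the means and library sizes of this comparison with 2 libraries a group. Each gene was drawn independently of the others. Only 66 or 67 genes were changed at each fold, where 10.12% of genes were called in the data, so the shares below may differ there. Over 13063 genes, edgeR recovered 6.06% of genes changed by a fold of 1.5, 53.7% of those changed by a fold of 2 and 92.5% of those changed by a fold of 4, and 9.74% of its calls were unchanged genes. In the simulated lists, a truly shifted list gave an adjusted p of 3.25e-36 with the preset correlation, 0.136 with an estimated correlation and 0.0178 with fry. These lists held no correlation between genes, while that estimated in the data reached 0.858 for the list of E2F targets and DNA replication. The simulation therefore does not show how the preset correlation performs on correlated lists.

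Alternatives were other scalings, other filters on low counts, robust dispersion, DESeq2 1.42.0, limma-voom, limma on log2(FPKM + 1) and log2(FPKM + 0.1), a minimum fold of 1.5 (glmTreat), an adjusted p below 0.01, removal of mitochondrial genes and the 10 most abundant other genes, and leaving out each library in turn. With 1 library left in a group, the fit assumes that it varies like the other group. Figures were drawn with matplotlib 3.10.9.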

Results

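RNA sequencing measured transcript levels in naive CD4+ T cells from the spleens of C57BL/6 mice after 3 days in culture under conditions that drive differentiation into regulatory T (Treg) cells, which restrain immune responses. The 4 libraries formed 2 groups. The wild-type libraries carried the numbers 13 and 15, and the knockout-labelled libraries, whose genotype is given as Setd2 with a CD4-driven Cre recombinase, carried the numbers 22 and 24. Setd2 encodes the histone methyltransferase that places trimethylation on lysine 36 of histone H3. The title of the series names autoimmunity driven by T cells and phospholipid remodelling by Lpcat4, so the comparison asks which transcripts differ between cultures labelled with the Setd2 deletion and wild-type cultures. Library totals were 16030869 counts for wild type 13, 14599957 for wild type 15, 15594506 for knockout-labelled 22 and 15653717 for knockout-labelled 24, and a level of 3 counts equalled 0.184 to 0.201 CPM (counts scaled to a common library size). The labels do not state whether the libraries of a group came from separate animals, so the p-values measure the spread between these libraries, which may be technical.

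The targeted gene was examined first. Setd2 (ENSMUSG00000044791, chromosome 9, 110532597 to 110618633, plus strand, GRCm38) stood at 137 CPM in wild type 13, 146 CPM in wild type 15, 137 CPM in knockout-labelled 22 and 113 CPM in knockout-labelled 24. The group means were 141 ± 6.21 CPM (SD, n = 2) and 125 ± 16.9 CPM (SD, n = 2), a log2 fold change of -0.17 (SE 0.14, adjusted p = 0.436), which was within the spread between replicates. A count over the whole gene checks the deletion only as far as the deleted exons contribute reads, and the labels do not name those exons. The groups are therefore called wild type and knockout-labelled throughout.

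Foxp3, the transcription factor that defines Treg cells, was 4.53-fold lower in the knockout-labelled libraries, and Il17a, the cytokine of T helper 17 (Th17) cells, was 3.86-fold higher. Foxp3 (ENSMUSG00000039521, chromosome X, 7579676 to 7595243) measured 244 ± 3.82 CPM in wild type and 53.8 ± 31 CPM in the knockout-labelled group (SD, n = 2 each; log2 fold change -2.18, SE 0.37, adjusted p = 0.0233). Il17a (ENSMUSG00000025929, chromosome 1, 20730905 to 20734496) measured 69.8 ± 0.927 CPM and 269 ± 12.2 CPM (SD, n = 2 each; log2 fold change 1.95, SE 0.12, adjusted p = 0.00947). The killer-cell receptor gene Klrd1 and the repressor gene Bcl6 were also higher, and the DNA polymerase gene Pole, the asparagine synthetase gene Asns and the amino acid transporter gene Slc7a5 were lower. Slc7a5 did not pass the threshold without wild type 15 (adjusted p = 0.0785). The log2 fold change of Foxp3 was -2.94 without knockout-labelled 24, and its adjusted p was 0.0719 against a minimum fold of 1.5, the highest over its alternatives. Lpcat4, the acyltransferase named in the title, had a lower mean but did not pass the threshold.

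Across 13279 genes tested with edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment, 734 were higher and 610 lower in the knockout-labelled libraries, which is 10.12% of the genes. The excess of higher genes turned when libraries were scaled by their totals (674 higher and 771 lower) and was not seen with limma on log2(FPKM + 1) (445 higher and 446 lower). In the main test, 399 of the 734 higher and 259 of the 610 lower genes differed by a fold of 2 or more. The first principal component held 69.49% of the variance and placed both wild-type libraries on one side and both knockout-labelled libraries on the other. For 63.85% of all genes the groups did not overlap, where chance gives 33.33% for a single gene. Genes move together, so any main difference that sets these pairs of libraries apart would raise this share, whatever its cause. Leaving out wild type 13 reduced the counts to 192 higher and 129 lower and leaving out wild type 15 to 120 and 70, while leaving out knockout-labelled 24 raised them to 2122 and 2002 and leaving out knockout-labelled 22 gave 994 and 899. Counts within the gene lists moved likewise, from 66 higher and 63 lower members to 29 and 15 without wild type 13, 20 and 9 without wild type 15, 99 and 83 without knockout-labelled 22 and 164 and 149 without knockout-labelled 24. Against a minimum fold of 1.5, 85 genes were higher and 35 lower.

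**Figure D1:**
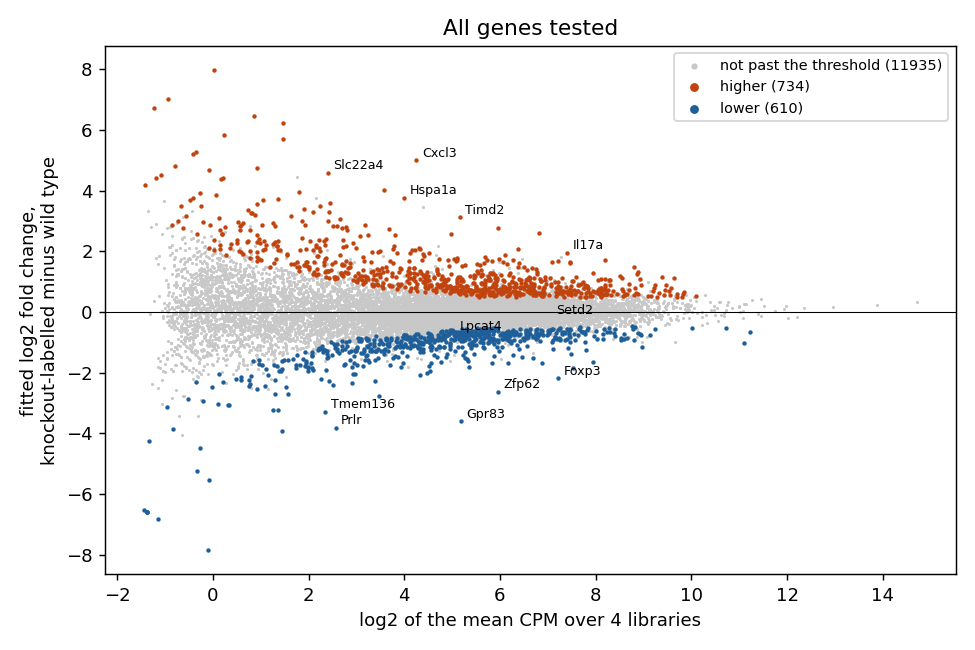
Each point is a gene, with the log2 of its mean CPM over the 4 libraries on the horizontal axis and the fitted log2 fold change, knockout-labelled minus wild type, on the vertical axis. Orange marks the 734 higher and blue the 610 lower genes; fitted values of genes with few counts depend on the prior count, and the labelled Foxp3 lies at -2.18 and Il17a at 1.95.

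Among the 29 measured Treg core genes, 5 rose, 5 fell and 19 did not pass the threshold (8 higher and 7 lower when adjusted over the list alone). With Foxp3, the genes that fell were Gpr83, a receptor abundant in Treg cells, from 66.9 CPM in wild type to 3.08 and 7.91 CPM in knockout-labelled 22 and 24, Izumo1r (folate receptor FR4), Itgae (the integrin CD103) and Il2ra, the high-affinity interleukin-2 receptor chain, from 1212 ± 26.3 to 843 ± 20.4 CPM (SD, n = 2 each; adjusted p = 0.0304; 0.166 without wild type 13 and 0.247 without wild type 15). Those that rose were Tigit (3.28-fold), Icos (2.24-fold), Tnfrsf9, Prdm1 and Nt5e, which encode receptors, a transcription factor and an ectoenzyme found on activated T cells. Izumo1r did not pass without wild type 13 (adjusted p = 0.0518), nor Itgae without wild type 15 (0.0952). Tnfrsf9, Prdm1 and Nt5e did not pass without wild type 13 (0.0631, 0.0705 and 0.339) or 15 (0.127, 0.126 and 0.224). The log2 fold changes of Ctla4 and Ikzf2 were 0.41 and 0.34 (adjusted p = 0.0702 and 0.103). The list as a set was not called by camera (adjusted p = 0.976). Its median log2 fold change was 0.00755, its mean -0.167 and the direction of its test up. The log2 fold change of Foxp3 was -1.68 without knockout-labelled 22 and -2.94 without knockout-labelled 24, and that of Gpr83 was -3.07 and -4.44.

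Th17 genes were higher as a set (camera, adjusted p = 0.00163), a call lost with an estimated correlation (adjusted p = 0.664 with an estimated correlation). The correlation estimated for this list was -0.0265, below the preset 0.01. This loss therefore does not show that correlated genes made the call. Of the 22 measured members 10 rose and 1 fell (12 and 1 when adjusted over the list alone; 4 and 0 without wild type 15). Besides Il17a these included Il17f, Rora, Ahr, Il1r1 and Il23r, the receptor chain for interleukin-23, from 0.817 to 10.03 CPM (log2 fold change 3.59, adjusted p = 0.022; 4.39 without wild type 13 and 2.81 without knockout-labelled 22). The member that fell was Il21. Without wild type 15 the adjusted p of Il17f, Rora, Ahr, Il1r1 and Il21 was 0.0603 to 0.192, and without wild type 13 that of Ahr and Il21 was 0.162 and 0.238. Without knockout-labelled 22 that of Il21 was 0.054 and the log2 fold change of Rora 0.963 against 1.63. Markers of gamma-delta and invariant T cells, some of which also make interleukin-17, moved with this list: 4 of 8 measured members rose and none fell (5 and 0 when adjusted over the list alone; camera, adjusted p = 0.00858; adjusted p = 0.664 with an estimated correlation). They were Cd163l1, from 0.422 to 6.55 CPM, Tcrg-C1 and Tcrg-C2, constant segments of the T-cell receptor gamma chain that resemble each other and may share reads, and Trgv2. Without wild type 15 the adjusted p of Tcrg-C1, Tcrg-C2 and Trgv2 was 0.0943, 0.137 and 0.178. That of Trgv2 was 0.139 without wild type 13 and 0.051 without knockout-labelled 24, and the log2 fold change of Tcrg-C1 was 1.35 without knockout-labelled 24 against 1.98. The delta constant segment Trdc measured 5.09 and 6.57 CPM in wild type and 10.1 and 5.81 CPM in knockout-labelled 22 and 24 (adjusted p = 0.374).

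Follicular helper T cell genes were higher as a set (camera, adjusted p = 0.024; adjusted p = 0.664 with an estimated correlation), with 4 of 12 members higher and none lower (5 and 0 when adjusted over the list alone). Bcl6, their defining repressor, rose 5.92-fold from 9.12 ± 1.14 to 54.1 ± 17.4 CPM (SD, n = 2 each; adjusted p = 0.0106), alongside Tox2, Pdcd1 and Cd40lg. Without wild type 15 the adjusted p of the set was 0.0587. T helper 1 genes gave 5 higher and 1 lower of 18 (camera, adjusted p = 0.396). Il18rap, Il18r1, Havcr2, Stat4 and Bhlhe40 rose and Eomes fell from 22.2 to 8.89 CPM, while Tbx21 had a log2 fold change of -0.40 (adjusted p = 0.23) and Ifng of -0.21 (adjusted p = 0.605). T helper 2 genes gave 2 higher (Nfil3, Epas1) and 1 lower (Il9) of 12 (camera, adjusted p = 0.171). Gata3 and Il4 had log2 fold changes of 0.19 and 0.27 (adjusted p = 0.362 and 0.692). Without wild type 15, Bcl6 and Il18rap stayed past the threshold, while the adjusted p of Tox2, Pdcd1, Cd40lg, Il18r1, Havcr2, Stat4, Bhlhe40, Eomes, Nfil3, Epas1 and Il9 was 0.054 to 0.226. Without wild type 13 that of Pdcd1, Cd40lg, Il18r1, Stat4, Bhlhe40, Eomes, Nfil3 and Il9 was 0.0509 to 0.221, and that of Il9 was 0.0712 without knockout-labelled 22.

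**Figure D2:**
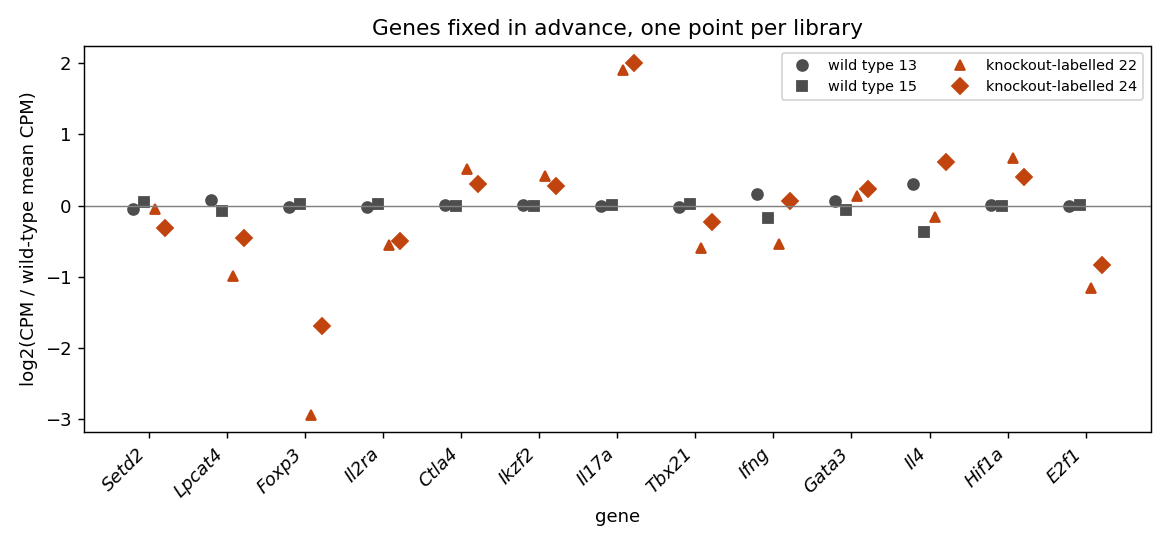
The vertical axis gives the log2 of each library's CPM over the wild-type mean for genes fixed before the data were examined, with grey circles and squares for wild type 13 and 15 and orange triangles and diamonds for knockout-labelled 22 and 24. Both knockout-labelled libraries lie below wild type for Foxp3, Il2ra and E2f1 and above it for Il17a and Hif1a, and knockout-labelled 22 lies between the wild-type libraries for Setd2.

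Inhibitory receptor and cytotoxic genes were higher as a set (camera, adjusted p = 0.000705; adjusted p = 0.664 with an estimated correlation). Of 18 members 9 rose and 1 fell (11 and 1 when adjusted over the list alone; 5 and 0 without wild type 15). Klrd1, which encodes the CD94 receptor chain, rose 3.70-fold from 29.3 ± 1.29 to 109 ± 2.56 CPM (SD, n = 2 each; log2 fold change 1.89, SE 0.13, adjusted p = 0.00947). Gzma, a granzyme protease, rose from 31.8 ± 3.13 to 135 ± 33.5 CPM, and Klrc1, Klrk1, Havcr2, Lag3, Tigit, Pdcd1 and Gzmc also rose. The granule gene Nkg7 fell from 65.5 to 36.4 CPM. Lag3, Pdcd1, Gzmc and Nkg7 did not pass without wild type 13 (adjusted p = 0.0746 to 0.134) or 15 (0.0985 to 0.224), nor Havcr2 without wild type 15 (0.0708). Klrd1, Klrc1, Klrk1 and Gzma, which activated CD4 T cells can also express, stand in lists of other cell types as well. Of 6 markers of CD8 T cells, Klrd1, Klrc1 and Klrk1 rose (3 higher also when adjusted over the list alone; camera, adjusted p = 0.0523), while Cd8a measured 101 CPM in wild type and 77.1 CPM in the knockout-labelled group (adjusted p = 0.583). That list passed under 5 alternatives, with adjusted p = 0.0421 at a filter of 5 CPM, 0.0384 with upper-quartile scaling, 0.0316 with the library total, 0.0164 without wild type 15 and 0.0143 without knockout-labelled 24, in a range up to 0.664. Markers of natural killer (NK) and innate lymphoid cells gave 3 higher of 10 (4 when adjusted over the list alone; camera, adjusted p = 0.00942; adjusted p = 0.664 with an estimated correlation; 0.0862 without knockout-labelled 22), namely Klri2, Gzma and Klre1, the last not past the threshold without wild type 13 (0.204), wild type 15 (0.0914) or knockout-labelled 22 (0.0716). B cell markers were higher as a set (camera, adjusted p = 0.00163; adjusted p = 0.664 with an estimated correlation) at low levels: of 15 members Igkc rose, from 2.51 to 7.43 CPM (6 higher when adjusted over the list alone; adjusted p of Igkc 0.0513 without wild type 13 and 0.144 without wild type 15).

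Genes of DNA replication driven by E2F factors were lower as a set with camera's preset correlation (adjusted p = 4.05e-11), a call lost with an estimated correlation (adjusted p = 0.664 with an estimated correlation) and with fry (adjusted p = 0.161). All 38 measured members had fitted values below 0, with a median log2 fold change of -0.772, and 19 fell while 19 did not pass the threshold (4 fell without wild type 13, 2 without wild type 15 and 37 without knockout-labelled 24; 30 when adjusted over the list alone). Pole, the catalytic subunit of DNA polymerase epsilon, fell from 259 ± 31.6 to 99.3 ± 4.07 CPM (SD, n = 2 each; log2 fold change -1.38, SE 0.14, adjusted p = 0.0103). E2f8 fell 2.21-fold, Dnmt1, the maintenance DNA methyltransferase, 1.91-fold, and E2f1 1.99-fold (adjusted p = 0.0116, 0.0177 and 0.0199). Without wild type 15 the adjusted p of Dnmt1 was 0.092 and that of E2f1 0.0929, and without wild type 13 that of E2f1 was 0.0609. The list medians per library lay -0.974 and -0.527 from the wild-type mean in knockout-labelled 22 and 24. The correlation estimated for this list was 0.858, above the preset 0.01, so the preset p may be too small. Mitosis genes went both ways, with 3 higher (Cdc20, Cenpa, Ube2c) and 2 lower (Foxm1, Mki67) of 28 (camera, adjusted p = 0.516). Targets of p53 were higher as a set (camera, adjusted p = 0.0192; adjusted p = 0.664 with an estimated correlation; 0.16 without wild type 15 and 0.0834 without knockout-labelled 24). Of 24 members, Perp, Pmaip1, Gadd45a and Btg2 rose and none fell (7 and 0 when adjusted over the list alone). The correlation estimated for the p53 targets was 0.268, above the preset 0.01, so the preset p may be too small. The named mitosis genes and Pmaip1, Gadd45a and Btg2 did not pass without wild type 13 (adjusted p = 0.0501 to 0.178) or 15 (0.123 to 0.354), nor Perp without wild type 15 (0.0666) or Mki67 without knockout-labelled 22 (0.0519).

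**Figure D3:**
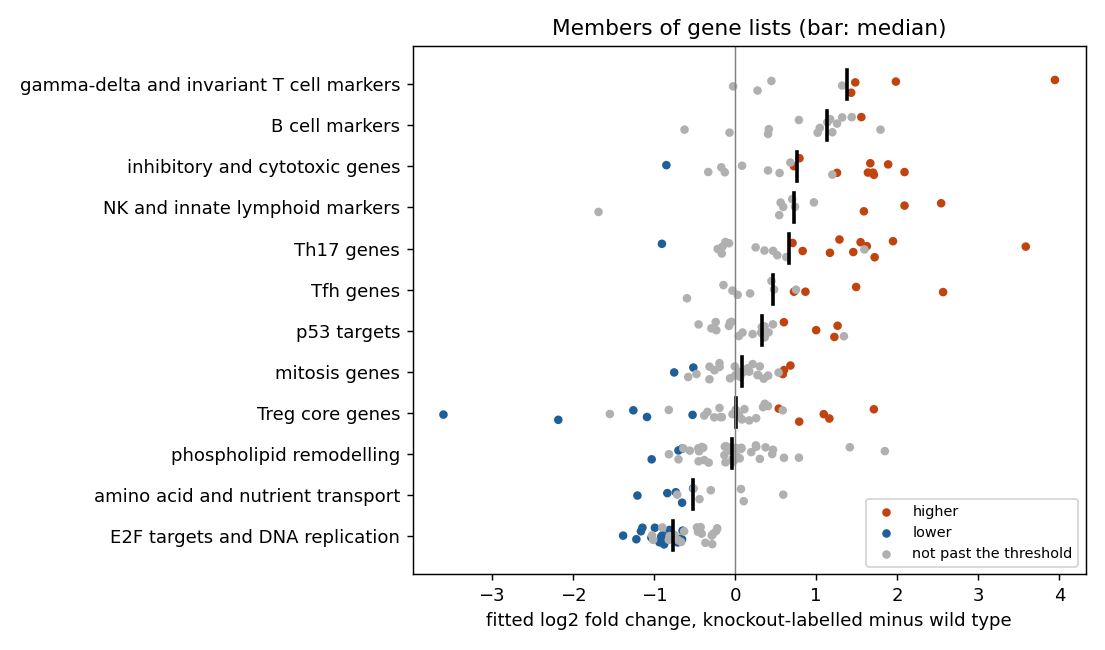
Each point is a gene of a list, placed by its fitted log2 fold change, knockout-labelled minus wild type, with black bars at the list medians; orange points rose, blue points fell and grey points did not pass the threshold. The 38 E2F and replication genes all lie below 0 around a median of -0.772, while the 29 Treg core genes spread to both sides of a median of 0.00755.

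Amino acid and nutrient transporters were lower as a set (camera, adjusted p = 0.0173; adjusted p = 0.664 with an estimated correlation; 0.0587 without wild type 15 and 0.161 without knockout-labelled 24). Of 12 members 5 fell and none rose (8 lower and 1 higher when adjusted over the list alone), among them Slc7a5, the large neutral amino acid transporter, from 191 ± 30.5 to 83.0 ± 12.1 CPM (SD, n = 2 each; adjusted p = 0.0168; 0.0785 without wild type 15), and the glutamine carrier Slc1a5 (0.0399; 0.214 without wild type 13 and 0.388 without wild type 15). The list of unfolded protein and integrated stress response genes split, with 5 lower and 3 higher of 25 (camera, adjusted p = 0.584). Its lower members were Asns (asparagine synthetase, 3.17-fold), Trib3 (3.49-fold), Shmt2 and the serine synthesis enzymes Phgdh and Psat1. Its higher members were the endoplasmic reticulum chaperones Hspa5 and Hsp90b1 and the stress sensor Ern1. With each library left out in turn, the log2 fold change of Asns was -1.79 to -1.53 and that of Trib3 -2.01 to -1.58. Phgdh and Shmt2 did not pass without wild type 15 (adjusted p = 0.0538 and 0.13), nor did Psat1, Hspa5, Hsp90b1 and Ern1 without wild type 13 (0.0594 to 0.183) or 15 (0.162 to 0.295). Over the 294 KEGG pathways annotated in the deposited table, camera called 6 lower and 2 higher. The lower ones were DNA replication (adjusted p = 0.000262), the Fanconi anemia pathway, homologous recombination, mismatch repair, glycine, serine and threonine metabolism (adjusted p = 0.0346) and the one-carbon pool by folate, and the higher ones were ECM-receptor interaction (adjusted p = 0.0386) and antigen processing and presentation (adjusted p = 0.045). These 8 calls were lost as well (adjusted p = 0.911 with an estimated correlation).

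Lpcat4 (ENSMUSG00000027134, chromosome 2, 112239468 to 112247111), which attaches fatty acids to lysophospholipids, measured 40.7 ± 3.02 CPM in wild type and 25.1 ± 6.51 CPM in the knockout-labelled group (SD, n = 2 each; log2 fold change -0.70, SE 0.20, adjusted p = 0.0712). Both knockout-labelled libraries lay below both wild-type libraries, and the adjusted p ranged from 0.00799 without knockout-labelled 24 to 0.745 against a minimum fold. Of 40 measured phospholipid remodelling genes, 3 fell and none rose (3 lower also when adjusted over the list alone; camera, adjusted p = 0.396). These were the acyltransferases Lpgat1, from 81.6 to 50.3 CPM, Agpat3, from 259 to 165 CPM, and Gpam, from 13.9 to 6.81 CPM. None of the 3 passed without wild type 13 (adjusted p = 0.128, 0.155 and 0.122) or without wild type 15 (0.196, 0.243 and 0.162). In other lipid lists, 1 of 24 cholesterol synthesis genes rose (Mvd), 1 of 18 fatty acid synthesis genes rose (Fads2, a fatty acid desaturase, from 8.06 to 26.0 CPM) and 1 of 20 fatty acid oxidation genes fell (Decr1). Mvd and Decr1 did not pass without wild type 13 (adjusted p = 0.131 and 0.203) or 15 (0.16 and 0.328).

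Hif1a, the hypoxia-inducible factor subunit, rose 1.45-fold (adjusted p = 0.044; 0.203 without wild type 13 and 0.269 without wild type 15), and 3 of 30 glycolysis and HIF1 target genes rose (Aldoa, Hif1a, Kdm3a) while 2 fell (Vegfa, Hk1). Of 20 interleukin-2 and STAT5 response genes 5 fell, including Myc, Bcl2, which protects cells from apoptosis, and the cyclin Ccnd2, and Pim2 rose. Il7r, the interleukin-7 receptor, rose 2.51-fold. Among 34 activation genes 3 rose and 3 fell, with the early growth response factor Egr1 among the latter. Of 13 mitochondrially encoded genes 4 fell, among them mt-Cytb from 2931 to 1460 CPM, although the mitochondrial share of all counts was 4.96%, 5.06%, 5.02% and 5.03% in wild type 13 and 15 and knockout-labelled 22 and 24. Kdm3a, Vegfa, Hk1, Myc, Bcl2, Ccnd2 and Pim2 did not pass without wild type 13 (adjusted p = 0.0534 to 0.248) or 15 (0.124 to 0.31), nor mt-Cytb without wild type 15 (0.0733). Camera called none of these lists at the threshold, nor any other of the 32 lists tested that is not named above as called. With 1 library left out, the adjusted p fell to 0.0428 for mitochondrially encoded genes (without wild type 13), 0.00432 for interferon-stimulated genes (without knockout-labelled 22) and 0.0334 for cholesterol synthesis (without knockout-labelled 24), in ranges up to 0.664, 0.818 and 0.666 over all alternatives.

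By size, the 8 largest rises under the rule for named genes were Cxcl3, Slc22a4, Hspa1a, Il23r, Timd2, Cd36, Csgalnact1 and Ica1. For rises and falls alike, that rule takes only genes past the threshold with a mean of 5 CPM or more and non-overlapping groups. It leaves out predicted names such as 5830411N06Rik, whose log2 fold change was 4.02. Cxcl3, a chemokine that attracts neutrophils, measured 1.53 and 0.738 CPM in wild type and 53.3 and 20.7 CPM in knockout-labelled 22 and 24 (log2 fold change 5.002, SE 0.58, adjusted p = 0.0116; 5.63 without wild type 13 and 4.18 without knockout-labelled 22). Timd2, a receptor for ferritin, rose 8.69-fold to 63.9 ± 10.9 CPM (SD, n = 2), and Cd36, a fatty acid transporter, rose from 1.15 to 9.39 CPM. The heat shock gene Hspa1a stood at 52.5 CPM in knockout-labelled 22 and 7.21 CPM in knockout-labelled 24, and its log2 fold change of 3.77 was 1.73 without knockout-labelled 22 and 4.58 without knockout-labelled 24, with adjusted p = 0.0478 against 0.0556 and 0.066 without wild type 13 and 15. It has a near-identical copy with which it may share reads. The 8 largest falls included Prlr, the prolactin receptor, from 11.1 to 0.786 CPM, Gpr83, Tmem136, Zfp62, Fbln2, Cth and Stc2. Zfp62, a zinc finger gene, fell from 107 ± 23.6 to 17.4 ± 4.79 CPM (SD, n = 2 each; log2 fold change -2.62, SE 0.24, adjusted p = 0.00947), and Cth, which makes cysteine, from 12.6 to 2.48 CPM. Stc2 did not pass without wild type 15 (adjusted p = 0.0917), and its log2 fold change was -3.06 without knockout-labelled 24 against -2.27.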

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

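Alternatives for pathways, and upper-quartile and library-total scaling for gene lists, were chosen after seeing the data; all others were fixed before. Scaling by size factors, upper quartile or library total gave 674 to 756 higher and 590 to 771 lower genes. Without a filter there were 1261 higher and 1088 lower genes and 109 higher list members. limma on log2(FPKM + 1) and log2(FPKM + 0.1) gave 445 and 457 higher and 446 and 434 lower genes. A minimum fold of 1.5 left 85 higher and 35 lower genes, with 15 and 4 list members, and an adjusted p below 0.01 left 23 and 6 genes, with 6 and 1 list members, as both demand more of each gene. Lpcat4 passed the threshold without a filter (log2 fold change -0.6967, adjusted p = 0.0262) and with DESeq2 (-0.695, adjusted p = 0.0374), against a range of 0.00799 to 0.745 over its alternatives; the cause was not tested. With an estimated correlation 0 of the 9 called gene lists and 0 of the 8 called pathways passed, and with fry 0 lists, where 0 and 8 lists had an unadjusted p under 0.05 with an estimated correlation and with fry; 30 lists passed fry's test of change in either direction. Leaving out each library in turn gave 120 to 2122 higher and 70 to 2002 lower genes (192 and 129 without wild type 13, 120 and 70 without wild type 15, 994 and 899 without knockout-labelled 22, 2122 and 2002 without knockout-labelled 24). It also gave 20 to 164 higher and 9 to 149 lower list members, 7 to 11 gene lists, 3 to 9 pathways (3 without wild type 15, 4 without knockout-labelled 22), and log2 fold changes of -0.9956 to -0.4458 for Lpcat4 and -0.3078 to -0.04627 for Setd2. Of the 93 named genes past the threshold, 0 changed direction under any alternative and 37 stayed past it without each library in turn, Foxp3 and Il17a among them. Without a knockout-labelled library, the only replicate spread left is that of the wild-type pair, so passing those fits is weak support. For Foxp3 that SD was 3.82 CPM, against 31 CPM in the knockout-labelled pair. Under all other settings except the 0.01 threshold, 31 of the 93 genes stayed past the threshold. Foxp3 did not pass against a minimum fold of 1.5 (adjusted p = 0.0719) or at 0.01 (0.0233). Genes not past the threshold that changed sign did so when a library was left out: Ifng -0.5393 to 0.07088, Il4 -0.1687 to 0.6461, Hbb-bs -0.3947 to 0.1332, Itga2b -0.07947 to 0.2433 and Col1a1 -0.9066 to 0.1288. Rounding counts down was not run, since the deposited counts are whole. No paired analysis was possible because the groups share no replicate number.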

Other observations

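The gene families and the tests in this part were chosen only after the results were seen, except the gene lists, which were fixed before. Of 15 tested killer-cell lectin-like receptor (Klr) genes, all on chromosome 6, 7 were higher in the knockout-labelled libraries and 8, among them Klrb1c (0.918 to 1.55 CPM, adjusted p = 0.417), did not pass the threshold; 15 more in the table were too low to test. The median log2 fold change of the 15 tested genes was 0.87 (camera for this set alone, unadjusted p = 1.38e-05, and p = 0.173 with an estimated correlation). The 7 higher genes, Klrc1, Klrc2, Klrc3, Klrd1, Klrk1, Klre1 and Klri2, lay between positions 129577905 and 129740484, and the other 8 tested genes lay outside this stretch. The 7 were picked because they passed, and their median was 1.89. Klrc2 went from 3.31 to 22.3 CPM and Klri2 from 4.08 to 23.8 CPM; Klrc1, Klrc2 and Klrc3 resemble each other and may share reads. Klrc3 and Klre1 did not pass without wild type 13 (adjusted p = 0.065 and 0.204) or 15 (0.102 and 0.0914), nor Klre1 without knockout-labelled 22 (0.0716). Beside the gamma-delta markers, the predicted scavenger receptor gene 5830411N06Rik measured 1.65 and 1.07 CPM in wild type and 19.8 and 25.0 CPM in knockout-labelled 22 and 24 (log2 fold change 4.02, adjusted p = 0.00947), and Tcrg-V4 rose from 1.03 to 4.28 CPM (adjusted p = 0.0215; 0.0866 without wild type 13 and 0.0952 without wild type 15).

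Of 189 families of genes that share a symbol stem and hold at least 8 tested genes, camera called 4. Variable segments of the T-cell receptor alpha chain (Trav) were lower, with 47 of 58 fitted below 0 and a median log2 fold change of -0.402 (adjusted p = 0.00918; adjusted p = 0.969 with an estimated correlation), though 0 single genes passed edgeR's threshold. Their summed level was 169.9 and 170.8 CPM in wild type and 121.2 and 125.5 CPM in knockout-labelled 22 and 24, while summed beta variable segments measured 318.4, 299.2, 274.9 and 300.4 CPM. Unlike other CPM here, these sums used the library totals without the scaling factors. The factor of 0.959 for knockout-labelled 22 would raise its values. Mcm replication genes (median -0.495) and Zfp zinc finger genes (median -0.184, 17 lower and 6 higher of 314, adjusted p = 0.0315) were lower, and ribosomal Rpl genes (median 0.204, 2 higher of 55, adjusted p = 0.0427) were higher. These 3 calls were lost as well (adjusted p = 0.969 with an estimated correlation), and the 4 medians kept their signs under each scaling.

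The 38 E2F and replication genes, of which 19 fell and 19 did not pass the threshold, had a median log2 fold change of -0.772. Their call as a set was lost with an estimated correlation (adjusted p = 0.664 with an estimated correlation) and with fry (adjusted p = 0.161). Fewer dividing cells would lower mitosis genes by about as much, and their median was 0.0854 with an SD of 0.376, which argues against that as the whole cause. That SD is across genes that move together (estimated correlation 0.392). Of the 28 mitosis genes 3 rose and 2, Foxm1 and Mki67, fell, so a part played by fewer dividing cells stays open. A trend with GC content over all genes, read at these 38 genes, was 0.0188 on the log2 scale and nowhere outside 0.000447 to 0.08, which argues against GC content. Setd2 genotype stays open and untested, as do differences in culture or cell state between these libraries.

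Transcripts of the 7 killer receptor genes could come from other cells in the cultures, which began from naive CD4+ T cells. NK cells would bring Tyrobp, Fcer1g and Klrb1c, yet the highest of their knockout-labelled means was 3.32% of that of Klrd1, which argues against NK cells, although Gzma rose. CD8 T cells cannot be told apart from a change within CD4 T cells: the higher of Cd8a and Cd8b1 stood at 71.0% of Klrd1, a baseline already present in wild type that could hide a small share. Cd8a stood at 81.0, 120, 113 and 41.2 CPM in wild type 13 and 15 and knockout-labelled 22 and 24. Over the wild-type mean, Cd8a gained 12.4 and -59.5 CPM and Cd8b1 15.8 and -16.1 CPM in knockout-labelled 22 and 24, where Klrd1 gained 77.5 and 81.1 CPM. The CD8 genes thus rose in knockout-labelled 22 but fell in knockout-labelled 24, while Klrd1 rose in both. Gamma-delta T cells cannot be told apart either: Trdc stood at 7.33% of Klrd1 and gained 5.52% and -0.0271% of the CPM that Klrd1 gained in knockout-labelled 22 and 24, which goes against them, but Tcrg-C1 and Tcrg-C2 stood at 14.7% and 16.7% and gained in both libraries. Genotype stays open as well, untested apart from these.

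Some genes jumped between libraries against genotype. Among 9302 genes above a mean of 10 CPM, 76 had a gap of over 1 on the log2 scale, with a spread under 0.5 on each side, that set 1 library or a mixed pair apart, for instance Ablim1 at 179, 743, 817 and 135 CPM and Tmem127 at 150, 146, 109 and 9.13 CPM in wild type 13 and 15 and knockout-labelled 22 and 24. Such gaps followed genotype in 91 genes and the mixed pairings in 5 and 6, and 3 pairings are too few for a share under 0.05. The odds ratio for overlapping another gene was 1.22 against other genes (95% limits 0.754 to 1.98), so reads shared with an overlapping gene cannot be told apart from other causes. The median length was 8081 bases against 5728.5 in other genes (permutation test, two-sided, p = 0.00106). That permutation did not match genes for level. The limit on spread may favour genes with more counts, so the length difference may come from the selection. How the authors' counting assigned reads among isoforms or similar sequences was not tested and stays open, and no biological explanation was tested.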
